A study of Sinorhizobium meliloti with 8 samples.

How the data were processed

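Total RNA of 8 Sinorhizobium meliloti cultures was sequenced as single reads on an Illumina HiSeq instrument, per the labels. The cultures were of strains RmG212 (pckR+) and RmK124 (pckR::ΩSp, here pckR-) on 15 mM glucose or 15 mM succinate in M9 medium, and were harvested at the same optical density, per the labels' protocols. The group of each library was taken from its title, and each of the 4 groups has 2 libraries. The submitters call them biological duplicates.

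The authors deposited a single table for the series, with 6699 rows. Of these 6218 are named genes (3359 on the chromosome, 1290 on the plasmid pSymA and 1569 on the plasmid pSymB), 1799 of them with a gene symbol, and 481 are predicted RNAs, 110 of them antisense. The table has 0 rows of ribosomal or transfer RNA. Its raw count columns hold whole-number read counts per row and library, per the file headers. Its columns of normalized counts, of RPKM per group and of expression per group were deposited as whole numbers and were treated as a score, since the authors rounded them and their scale is not explained. They were not used as measurements, except that the factor between deposited raw and normalized counts of each library served as another scaling. The p-values and q-values of the authors' deposited table compare pairs of groups, and which test and which adjustment gave them is not given in the sources used here. The aligner, the counting program, the genome build, the strandedness of the libraries and the treatment of reads with several matches are likewise not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense RNAs are therefore uncertain. Coordinates are those of the deposited table, which numbers the replicons on; the positions printed are all on the chromosome. The reference table at hand is of another strain, matched 0 locus tags and was not used, and no genome sequence was used here.

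The comparisons used the raw counts of named genes. Predicted RNA rows, which took between 5.34% and 7.19% of the counts of a library, stayed out of library sizes and tests there, and were tested only in a fit with these rows kept in. With all rows, the libraries had 5725197 and 3476168 counts (pckR+ glucose), 4170050 and 8156775 (pckR- glucose), 6207705 and 3496281 (pckR+ succinate) and 5669028 and 4344898 (pckR- succinate). With R 4.3.3 and edgeR 4.0.16, genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 5815 genes and removed 403. Libraries were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all 8 libraries with robust estimation (common biological coefficient of variation 0.0776, 4 residual degrees of freedom, median prior degrees of freedom 14.3). Quasi-likelihood F-tests gave 5 comparisons: pckR- against pckR+ on glucose and on succinate, succinate against glucose in pckR+ and in pckR-, and the interaction. P-values were adjusted after Benjamini and Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM used TMM-scaled library sizes, and means are given with the SD of 2 libraries. SD, SE and p-values rest on 2 cultures per group.

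A total of 21 lists of genes, fixed before the data were examined from textbook knowledge of rhizobial metabolism and matched by symbol, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over all lists and comparisons. The lists were glycolysis and gluconeogenesis, the Entner-Doudoroff pathway, the pentose phosphate pathway and CO2 fixation, the TCA cycle and glyoxylate bypass, pyruvate dehydrogenase and malic enzymes, C4-dicarboxylate transport, glucose and alpha-glucoside uptake, other sugar and polyol catabolism, polyhydroxybutyrate and acetoacetate metabolism, succinoglycan synthesis, galactoglucan synthesis, flagella and chemotaxis, ribosomal proteins, ATP synthase, the respiratory chain, iron uptake, nitrogen assimilation, the phosphate starvation response, heat shock and general stress, nodulation and nitrogen fixation, and protocatechuate and aromatic catabolism. The symbol ibpA also falls in the list of other sugars and polyols, although its product is a heat shock protein. With a correlation estimated from the data no list passed in any comparison, the smallest adjusted p being 0.0805, against 55 of 105 pairs of list and comparison at the preset correlation (8, 11, 12, 13 and 11 in the order of the comparisons above), not all of which are described. That count of 0 depended on single libraries: it was 5 without pckR+ glucose replicate 1 (smallest adjusted p = 0.0218) and 4 without pckR+ glucose replicate 2 (0.0213), all of them tests of the Entner-Doudoroff or the flagellar and chemotaxis list. fry, which tests whether a list moves one way and does not set it against other genes, passed 66 of them. With an estimated correlation camera also uses the 4 residual degrees of freedom, so its larger p does not measure correlation between genes alone. For the Entner-Doudoroff list on glucose the estimate was -0.063, under the preset 0.01. Its unadjusted camera p still rose from 6.87e-16 to 0.00111.

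The rule for the genes named in the text was also fixed before the data were examined. It takes pckR and pckA; the 10 genes with the largest positive and the 10 with the largest negative change of each comparison of 2 groups, among called genes whose libraries do not overlap between the groups; the 5 largest in each direction for the interaction; and of each list up to 4 called members with the largest change, or any member for glycolysis, Entner-Doudoroff, C4-dicarboxylate transport and pyruvate dehydrogenase. Genes named outside this rule are described as chosen after their values were seen.

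The tests were checked on simulated counts with the library sizes of the real libraries. Each gene had its mean over all 8 libraries and the same dispersion in all groups. The wider spread between the pckR+ glucose replicates (chi-square per degree of freedom 10.9, against 2.52 to 3.15 in the other groups) was not modelled. The recovery on glucose therefore cannot be set against that on succinate. As a test list 40 genes were raised by 1.5-fold, and these are not in the recovery counts. Apart from them 67 genes were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold among 5815 genes. edgeR recovered 49, 62 and 64 of them for the strain effect on glucose, with 13 unchanged genes called, and 48, 59 and 63 for that on succinate, with 17 unchanged genes called. It recovered 31, 57 and 65 for the carbon source effect in pckR+, 41, 61 and 63 for that in pckR-, and 14, 46 and 64 for the interaction. Intervals and floors of counts would cover counting error only, and none is used for the genes named, whose errors are spreads between libraries.

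As alternatives, results were recomputed with size factors of DESeq2, with library totals, with the deposited scaling, with DESeq2 1.42.0 and its Wald test, with limma-voom, without a filter on low counts, with the groups compared alone, with the replicate number as a block, at an adjusted p under 0.01, with predicted RNA rows kept in, and without each library in turn. The deposited scaling and the predicted RNA rows were added after seeing the data.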

Results

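Transcript levels of Sinorhizobium meliloti, a soil bacterium that fixes nitrogen inside the root nodules of legumes, were measured by RNA sequencing in 8 libraries. The libraries came from 2 strains. RmG212 carries an intact pckR gene and is written pckR+ here, and RmK124 carries an ΩSp insertion in pckR and is written pckR-. Each strain was grown with shaking in M9 minimal medium with 15 mM glucose, a sugar that is broken down, or 15 mM succinate, a C4-dicarboxylic acid from which sugars have to be made by gluconeogenesis. Each of the 4 groups held 2 libraries, described by the submitters as biological duplicates. The series title places the regulator in the control of glycolytic and gluconeogenic metabolism. The comparisons address which transcripts differed between the pckR+ and pckR- strains on each carbon source, and whether these differences depended on it. No library came from a strain with pckR restored. Loss of pckR therefore cannot be told apart from other differences between the 2 strains.

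The counts on named genes summed to 5410993 and 3278966 in the pckR+ glucose libraries, to 3938246 and 7709152 in the pckR- glucose libraries, to 5875992 and 3290176 in the pckR+ succinate libraries and to 5263210 and 4032353 in the pckR- succinate libraries. A single count was worth between 0.129 and 0.298 counts-per-million (CPM) at these depths. No pair of replicates agreed within sampling noise. The chi-square per degree of freedom between replicates was 10.9 for pckR+ on glucose, 2.52 for pckR- on glucose, 3.15 for pckR+ on succinate and 2.61 for pckR- on succinate. The pckR+ glucose libraries differed by more than 2-fold at 31 genes, against 4, 10 and 11 genes in the other groups in the same order. These counts left out genes with a low mean CPM in the group. In a principal component analysis the first component held 59.6% of the variance, the second 21.9% and the third 6.67%, and pckR+ glucose replicate 1 lay at -16.6 on the third component. Among the genes that differed between the pckR+ glucose libraries was znuA, which encodes a part of a high-affinity zinc uptake system and was chosen after its values were seen. It had 93.5 CPM in replicate 1 and 3328 CPM in replicate 2, and the pckR+ succinate libraries, with 40.8 and 171 CPM, lay nearer to replicate 1.

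The pckR transcript (SMc02975, chromosome, 3097909 to 3096884 on the minus strand in the coordinates of the deposited table, whose genome build is not given in the sources used here) was low in each pckR- library. It had 81.2 and 76.3 CPM in pckR+ on glucose, 93.6 and 105.9 CPM in pckR+ on succinate, 3.34 and 3.47 CPM in pckR- on glucose, and 4.91 and 3.84 CPM in pckR- on succinate. pckR fell by 4.52 ± 0.145 (log2, SE, n = 2 libraries per group) in pckR- on glucose and by 4.47 ± 0.141 on succinate. The annotation calls its product a regulator of phosphoenolpyruvate carboxykinase. That enzyme, which makes phosphoenolpyruvate from oxaloacetate at the entry to gluconeogenesis, is encoded by pckA (SMc02562, chromosome, 52483 to 54093, plus strand). The pckA level was 35.1 ± 2.39 CPM (SD, n = 2) in pckR+ on glucose, 206 ± 23.4 in pckR- on glucose, 1374 ± 13.0 in pckR+ on succinate and 421 ± 19.2 in pckR- on succinate.

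**Figure D1:**
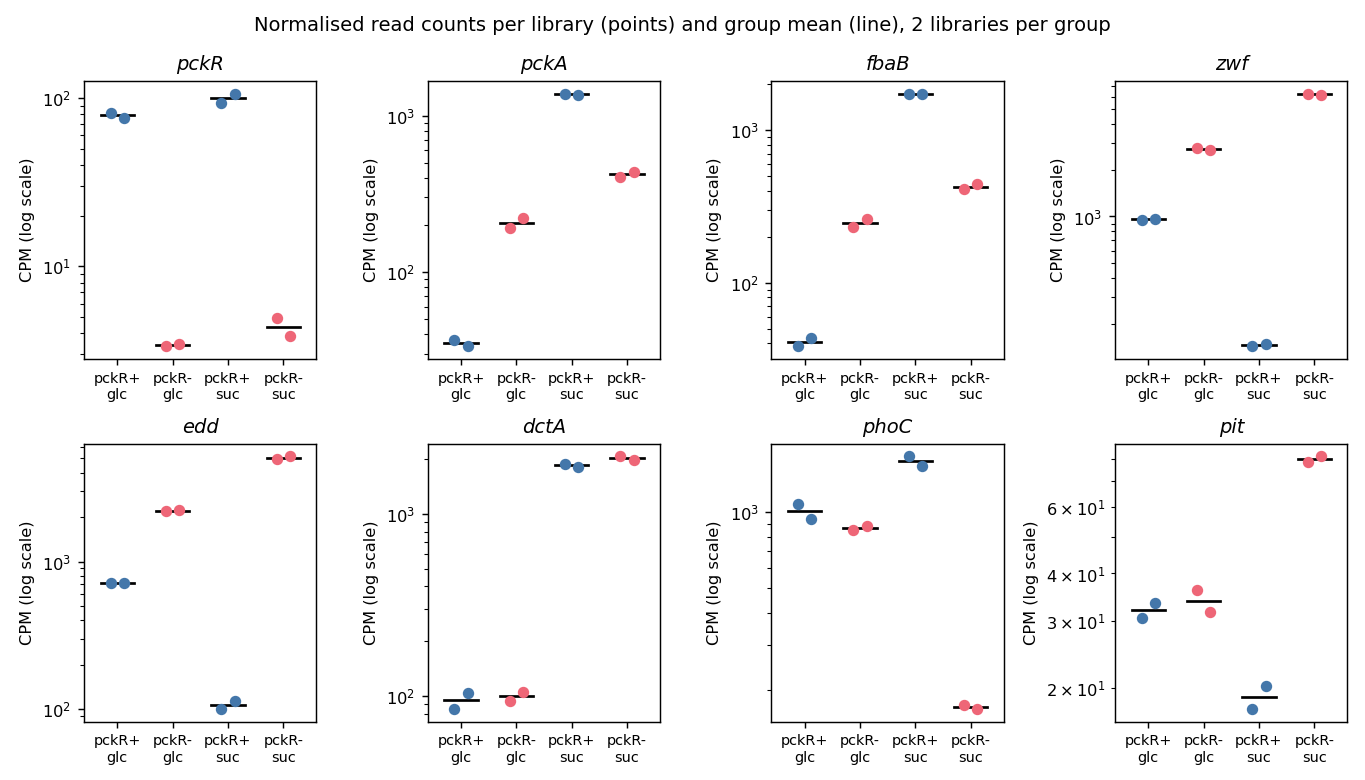
Levels of pckR, pckA, fbaB, zwf, edd, dctA, phoC and pit in each library, in CPM on a logarithmic axis, with points for libraries and a line for the mean of each group of 2. The pckR- libraries lie near 3.34 to 4.91 CPM for pckR, and pckA and fbaB lie above pckR+ on glucose and below it on succinate.

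On glucose, the genes that rose most in pckR- were pckA and fbaB. fbaB encodes a class I fructose-bisphosphate aldolase (SMc03983, chromosome, 2980339 to 2981364, plus strand) and went from 40.7 ± 3.52 CPM in pckR+ to 245 ± 20.0 CPM in pckR- (SD, n = 2). The log2 fold change was 2.60 ± 0.078 (SE, adjusted p = 3.72e-14) for fbaB and 2.55 ± 0.082 (adjusted p = 5.21e-14) for pckA. Genes of the Entner-Doudoroff pathway, the main route of glucose breakdown in this species, rose with them: edd (SMc03068, chromosome, 768454 to 766634, minus strand), encoding phosphogluconate dehydratase, by 1.62 ± 0.059, pgl by 1.54 ± 0.062, zwf (SMc03070, chromosome, 770728 to 769253, minus strand), encoding glucose-6-phosphate dehydrogenase, by 1.51 ± 0.052, and eda2 by 0.66 ± 0.072 on the log2 scale. Glucokinase (glk) and methylglyoxal synthase (mgsA) each rose by 0.62, with SE 0.067 and 0.086. SMc00404, annotated as a hypothetical protein, fell by 2.16 ± 0.086, from 231 ± 7.58 to 52.1 ± 3.74 CPM.

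Of the 8 tested Entner-Doudoroff genes 4 rose on glucose in pckR- (4 adjusted over the list alone), with a camera adjusted p = 1.80e-14 at the preset correlation and an adjusted p = 0.0805 with an estimated correlation. Of the 15 genes of glycolysis and gluconeogenesis 4 rose, pckA, fbaB, mgsA and glk (5 adjusted over the list alone; camera adjusted p = 1.11e-09, adjusted p = 0.0913 with an estimated correlation). Of the 51 flagellar and chemotaxis genes 9 rose, and 30 adjusted over the list alone (camera adjusted p = 1.55e-28, adjusted p = 0.0805 with an estimated correlation). That count of 9 was 14 without pckR+ glucose replicate 1, 1 without pckR- glucose replicate 1, 0 without pckR- glucose replicate 2, 5 with the scaling of the deposited normalized counts and 3 with DESeq2. The 26 succinoglycan genes had a median log2 fold change of -0.060, and camera passed the list downward (adjusted p = 0.000822, adjusted p = 0.176 with an estimated correlation). Of these 1 gene, exoH, fell, by 0.34 ± 0.068 (2 fell adjusted over the list alone), a call lost with DESeq2 and without pckR+ glucose replicate 1 (adjusted p = 0.135) or pckR- glucose replicate 2 (adjusted p = 0.455). Of the 47 nodulation and nitrogen fixation genes 0 passed edgeR's test or that of DESeq2 or limma-voom, and 0 adjusted over the list alone. Beside 495 of all 5815 genes with an unadjusted edgeR p under 0.05, a like share, 4 of these 47 had one. Their median was -0.10, and camera passed the list downward (adjusted p = 0.00249, adjusted p = 0.146 with an estimated correlation), but not without pckR+ glucose replicate 1 (adjusted p = 0.116) or replicate 2 (adjusted p = 0.0528). Of 26 respiratory chain genes and 21 heat shock and stress genes 0 passed edgeR's test or that of DESeq2 or limma-voom, with 4 and 5 at an unadjusted p under 0.05 and 0 and 3 adjusted over the list alone, and of 12 genes for glucose and alpha-glucoside uptake glk alone passed, which the glycolysis list also holds (1 adjusted over the list alone). Their medians were 0.064, 0.077 and 0.019, and camera passed these 3 lists upward at the preset correlation: the respiratory chain (adjusted p = 0.0106, adjusted p = 0.510 with an estimated correlation), heat shock and stress (adjusted p = 0.0263, adjusted p = 0.322 with an estimated correlation) and glucose and alpha-glucoside uptake (adjusted p = 0.0309, adjusted p = 0.204 with an estimated correlation). The first was lost without pckR+ glucose replicate 2 (adjusted p = 0.288) or pckR- glucose replicate 1 (0.401), the second without pckR+ glucose replicate 1 (0.402) or pckR- glucose replicate 2 (0.185), and the third without pckR+ glucose replicate 1 (0.0743), pckR+ glucose replicate 2 (0.0677) or pckR- glucose replicate 2 (0.0910). In all, edgeR's quasi-likelihood test passed 37 of 5815 genes in this comparison, 23 higher and 14 lower in pckR-, and 8 of them changed by more than 2-fold.

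The number of calls on glucose depended on single libraries: it was 111 without pckR+ glucose replicate 2 (32 of them by more than 2-fold), 19 without pckR- glucose replicate 1 and 11 without pckR- glucose replicate 2, and DESeq2 gave 17. The 10 genes pckR, pckA, fbaB, edd, pgl, zwf, eda2, glk, mgsA and SMc00404 stayed past the test without each of the 8 libraries in turn, and the other 27 were lost at least once. A q-value under 0.05 was given to 3243 named genes for this comparison in the authors' deposited table, all of them among the 5815 tested genes. Of the 37 genes called by edgeR, 24 (64.9%) had such a q-value, and the others did not. So long a list would share many of any 37 tested genes. The 24 alone therefore does not show agreement between the tests, and an excess over that share was not tested. How those q-values were made is not given in the sources used here.

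On succinate, pckR- had more of the Entner-Doudoroff transcripts and less of pckA and fbaB. zwf stood at 146 ± 3.45 CPM in pckR+ and 6231 ± 71.2 CPM in pckR- (SD, n = 2), a log2 fold change of 5.42 ± 0.062 (SE, adjusted p = 1.12e-21). edd rose from 107 ± 9.26 to 5056 ± 140.1 CPM, by 5.57 ± 0.071 on the log2 scale (adjusted p = 3.87e-21), pgl by 5.30 ± 0.075 and eda2 by 3.63 ± 0.081. mgsA rose by 3.05 ± 0.103 and glk by 2.57 ± 0.073. In the opposite direction, fbaB fell from 1724 ± 5.43 to 426 ± 23.3 CPM, a log2 fold change of -2.02 ± 0.068 (adjusted p = 1.76e-14), and pckA fell by 1.71 ± 0.070 on the log2 scale (adjusted p = 4.04e-13).

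Other genes of central carbon metabolism also changed on succinate. Of the 15 genes of glycolysis and gluconeogenesis 11 rose and 3 fell, and all 15 changed adjusted over the list alone (camera adjusted p = 0.000499, adjusted p = 0.218 with an estimated correlation). Among those that rose were pyruvate kinase (pykA, log2 fold change 1.37), phosphoglyceromutase (gpmA, 1.20), phosphoglycerate kinase (pgk, 1.15) and glucose-6-phosphate isomerase (pgi, 0.78). Of the 8 Entner-Doudoroff genes edd, zwf, pgl and eda2 rose and 2 fell, eda1 and gntK, with 6 changed adjusted over the list alone (camera adjusted p = 0.00037, adjusted p = 0.0917 with an estimated correlation). The 2 that fell were 0 without pckR+ succinate replicate 1 or pckR- succinate replicate 2, and 1 without pckR+ succinate replicate 2 or pckR- succinate replicate 1. Of the 13 genes of the pentose phosphate pathway and CO2 fixation 10 rose and 2 fell (rpiB and tkt1, chosen after their values were seen), and 12 changed adjusted over the list alone (camera adjusted p = 0.00361, adjusted p = 0.228 with an estimated correlation). The CO2 fixation genes among them were expressed at a low level: transketolase cbbT went from 5.14 ± 1.47 to 18.2 ± 6.53 CPM, a log2 fold change of 1.70 ± 0.264, and cbbX rose by 1.50 ± 0.171. In the list of pyruvate dehydrogenase and malic enzymes 5 of 6 genes rose, and 5 adjusted over the list alone, among them pdhAb (0.32), pdhB (0.31) and pdhAa (0.30), although camera did not pass it (adjusted p = 0.0576). The sixth gene, tme, fell with library totals or with the deposited scaling. Of the 18 genes of the tricarboxylic acid (TCA) cycle 13 rose, led by acnA with 1.03 ± 0.131, and 14 adjusted over the list alone (camera adjusted p = 0.00078, adjusted p = 0.257 with an estimated correlation). The 13 were 8 without pckR- succinate replicate 2, and also 8 with library totals or with the deposited scaling.

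**Figure D2:**
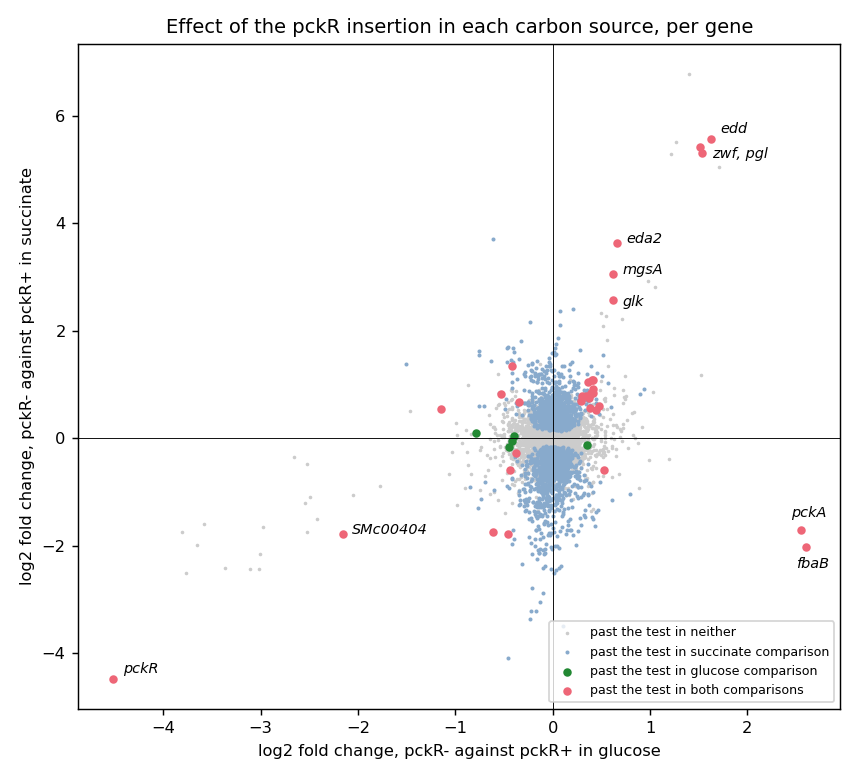
Log2 fold change of pckR- against pckR+ on succinate (vertical axis) over that on glucose (horizontal axis), with a point per tested gene and colours for the comparisons in which it passed the test. zwf, edd and eda2 lie at the upper right, pckR at the lower left, and pckA and fbaB at the lower right with 2.55 and 2.60 on glucose against -1.71 and -2.02 on succinate.

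Phosphate transport genes moved in both directions on succinate. The operon phoC, phoD, phoE and phoT encodes an ABC transporter of phosphate, and its substrate-binding protein phoD fell from 5337 ± 19.6 CPM in pckR+ to 644 ± 15.0 CPM in pckR- (SD, n = 2), a log2 fold change of -3.05 ± 0.071. phoE fell by 3.36 ± 0.068, phoC by 3.21 ± 0.073 and phoT by 3.21 ± 0.069. SMc03243, annotated as an alkaline phosphatase, fell by 4.09 ± 0.202, from 47.2 ± 4.91 to 2.75 ± 0.273 CPM. The phosphate transporter gene pit rose by 2.10 ± 0.111, from 18.9 ± 1.90 to 80.0 ± 2.02 CPM. Of the 11 tested genes of the phosphate starvation list 5 fell and 5 rose, and 10 changed adjusted over the list alone. The 4 pho transporter genes and phoR fell, while pit, pstC, pstA, pstB and phoU rose. phoR, pit, pstC, pstA, pstB and phoU were chosen after their values were seen. camera did not pass the list (adjusted p = 0.105), and passed it without pckR+ glucose replicate 1 (adjusted p = 2.13e-16), without pckR+ glucose replicate 2 (adjusted p = 6.58e-15) and without pckR+ succinate replicate 1 (adjusted p = 0.037). With an estimated correlation none of these 3 fits passed it (adjusted p = 0.0964, 0.115 and 0.270 in the same order). The count of 5 that rose was 3 without pckR- succinate replicate 2.

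Genes for surface polysaccharides and motility differed between the strains on succinate. Of the 26 genes for succinoglycan, the acidic exopolysaccharide this species needs to invade nodules, 21 rose in pckR- and 1 fell, and 22 changed adjusted over the list alone (camera adjusted p = 1.20e-09, adjusted p = 0.0805 with an estimated correlation). The galactosyltransferase exoY went from 407 ± 14.9 to 912 ± 30.4 CPM (SD, n = 2), a log2 fold change of 1.16 ± 0.061, exoV rose by 1.19 ± 0.082 and exoN by 1.10 ± 0.107, while the exporter gene exsA fell by 2.14 ± 0.113. With the deposited scaling 2 of these genes fell. Of the 20 genes for galactoglucan, the other exopolysaccharide of this species, 11 fell, and 11 adjusted over the list alone (camera adjusted p = 1.19e-05, adjusted p = 0.0805 with an estimated correlation). wgdA fell by 1.35 ± 0.162 and wgaB by 1.10 ± 0.141. cgmA, encoding a protein that modifies cyclic beta-1,2-glucan, rose by 3.70 ± 0.171, from 14.1 ± 0.416 to 184 ± 1.78 CPM. Of the 51 flagellar and chemotaxis genes 34 rose and 2 fell (mcpV and mcpW, chosen after their values were seen), and 37 changed adjusted over the list alone (camera adjusted p = 5.21e-11, adjusted p = 0.156 with an estimated correlation). Among them fliE rose by 1.08, motD by 1.04 and fliI by 0.91 on the log2 scale.

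Energy metabolism genes were higher in pckR- on succinate. All 10 ATP synthase genes rose, and 10 adjusted over the list alone (camera adjusted p = 6.53e-06, adjusted p = 0.0805 with an estimated correlation). atpA had a log2 fold change of 0.70, atpD of 0.69 and atpC of 0.68. Of the 26 respiratory chain genes 22 rose, and 22 adjusted over the list alone (camera adjusted p = 1.60e-08, adjusted p = 0.235 with an estimated correlation), among them nuoN (0.62), nuoM (0.61) and the cytochrome c oxidase gene ctaD (0.59). Ribosomal protein genes went the other way: 34 of 55 fell and 4 rose (rpmG, rpmF and, chosen after their values were seen, rpmB and rpmE), and 41 changed adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.653 with an estimated correlation). rplK had a log2 fold change of -0.39 and SMc04320, a protein of the small ribosomal subunit, of -0.95. The 34 were 13 without pckR+ succinate replicate 1 and 14 without pckR- succinate replicate 2. The 4 were 2 without pckR+ succinate replicate 2, 1 without each of the other 3 succinate libraries, 1 with library totals and 2 with the deposited scaling.

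Further lists changed in part on succinate, where 38.6% of all 5815 tested genes passed edgeR's test. The share that passed was under this for nitrogen assimilation and iron uptake, and above it for heat shock and stress. Of the 17 nitrogen assimilation genes 4 rose and 1 fell (ntrY, chosen after its values were seen), and 5 changed adjusted over the list alone (camera adjusted p = 0.394). The 4 that rose were glnT (1.19 ± 0.156), glnD (0.48), gltB (0.39) and gltD (0.38), and the count of 1 that fell was 0 without pckR+ succinate replicate 2 or pckR- succinate replicate 1, and 3 with library totals or the deposited scaling. Of the 21 heat shock and stress genes 5 rose and 9 fell, and 14 changed adjusted over the list alone (camera adjusted p = 0.266). Catalase katA fell by 1.60 ± 0.125, the chaperone genes ibpA by 0.73 and htpG by 0.60, and superoxide dismutase sodC rose by 0.78 on the log2 scale. The 5 that rose, sodC and, chosen after their values were seen, sodB, clpX, clpP2 and katB, were 3 with the deposited scaling. Of the 18 iron uptake genes 2 rose, rirA (0.73 ± 0.083) and irr (0.33), both encoding iron-responsive regulators, and 2 adjusted over the list alone (camera adjusted p = 0.181). Without pckR- succinate replicate 2 the count was 10 and camera passed the list (adjusted p = 0.00139, adjusted p = 0.430 with an estimated correlation).

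Over all 5815 genes, 2243 passed edgeR's test on succinate, 1187 higher and 1056 lower in pckR-, and 336 changed by more than 2-fold. The largest falls also included SM_b21377, SM_b21375 and SM_b21376, annotated as parts of a sugar ABC transporter, with log2 fold changes of -2.87, -2.78 and -2.51. DESeq2 passed 1468 genes. A q-value under 0.05 was given to 1376 named genes for this comparison in the authors' deposited table, 1005 of them among the 2243, so that table has fewer genes on succinate than the 3243 on glucose. With library totals in place of TMM the split was 879 higher and 1426 lower, and with the deposited scaling it was 861 higher and 1525 lower, with the median log2 fold change of all genes at -0.10 in place of -0.0031. The zinc uptake gene znuA was chosen after its values were seen. On succinate it had 40.8 and 171 CPM in pckR+ and 4782 and 4553 CPM in pckR-. It did not pass edgeR's test (adjusted p = 0.103), whose spread was estimated over all 4 groups. That spread takes in the pckR+ glucose libraries, which had 93.5 and 3328 CPM. Of 9 genes chosen in this way, 7 were annotated to zinc uptake or as copper proteins and 2 as hypothetical proteins. On succinate 0 of the 9 passed edgeR's test, and 5 passed with the 2 groups compared alone or with DESeq2.

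In pckR+, succinate against glucose raised dctA, pckA and fbaB. dctA encodes the transporter that takes up succinate, and went from 94.5 ± 13.9 to 1848 ± 46.5 CPM (SD, n = 2), a log2 fold change of 4.30 ± 0.092 (SE, adjusted p = 1.68e-14). fbaB rose by 5.41 ± 0.083 and pckA by 5.28 ± 0.087 (adjusted p = 8.30e-20). Among the genes that fell most, SM_b20902, annotated as the substrate-binding protein of a sugar transporter, went from 16786 ± 1052 to 217 ± 11.6 CPM, a log2 fold change of -6.27 ± 0.081 (adjusted p = 2.49e-20), and SMa0203, a substrate-binding protein, from 2536 ± 299.7 to 20.1 ± 3.07 CPM, by 6.96 ± 0.109. SMa0196, annotated as a gluconolactonase, fell by 5.58 on the log2 scale.

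The Entner-Doudoroff genes were lower on succinate in pckR+. Of 8 genes 5 fell, and 6 changed adjusted over the list alone (camera adjusted p = 1.33e-05, adjusted p = 0.0805 with an estimated correlation). The log2 fold change was -2.75 ± 0.064 for edd, -2.72 ± 0.056 for zwf and -2.04 for eda2, and -2.16 and -1.48 for mgsA and glk of the glycolysis list. Of the 12 genes for uptake of glucose and alpha-glucosides 10 fell, and 10 adjusted over the list alone (camera adjusted p = 6.12e-05, adjusted p = 0.0822 with an estimated correlation), among them aglE (-0.85), chvE (-0.67) and aglF (-0.52). Of the 6 C4-dicarboxylate transport genes dctA rose and 4 fell, and 5 changed adjusted over the list alone (camera adjusted p = 0.0842). The genes that fell included dctQ (-1.75), dctP (-1.51) and dctM (-1.06), parts of a second C4-dicarboxylate transporter. Of the 51 flagellar and chemotaxis genes 49 fell, and 49 adjusted over the list alone (camera adjusted p = 1.06e-36, adjusted p = 0.0805 with an estimated correlation). Chemoreceptor genes mcpZ and mcpX and the basal body gene flgF had log2 fold changes of -1.82, -1.73 and -1.59.

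Respiratory and TCA cycle genes were higher on succinate in pckR+. Of 26 respiratory chain genes 21 rose, and 26 adjusted over the list alone (camera adjusted p = 2.40e-10, adjusted p = 0.205 with an estimated correlation). The cytochrome o oxidase gene cyoB went from 17.5 ± 2.42 to 71.0 ± 7.80 CPM, a log2 fold change of 1.98 ± 0.130, and cyoA rose by 1.99. Of 18 TCA cycle genes 13 rose, and 14 adjusted over the list alone (camera adjusted p = 1.40e-05, adjusted p = 0.225 with an estimated correlation), among them the succinate dehydrogenase genes sdhB (0.64), sdhD (0.55), sdhA (0.55) and sdhC (0.54). Of 26 succinoglycan genes 17 rose and 2 fell (exoF3 and exoX, chosen after their values were seen), and 20 changed adjusted over the list alone (camera adjusted p = 9.05e-07, adjusted p = 0.0910 with an estimated correlation), with exoK at 0.76 and exoA at 0.73. edgeR passed 1644 genes in this comparison, 759 higher and 885 lower on succinate, 219 of them by more than 2-fold. DESeq2 passed 1006, and the larger side depended on the scaling: the split was 1029 higher and 769 lower with the deposited scaling, 869 higher and 830 lower with DESeq2's size factors, and 883 higher and 803 lower with library totals.

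In pckR-, succinate raised dctA as in pckR+, from 99.5 ± 8.79 to 2021 ± 68.5 CPM (SD, n = 2), a log2 fold change of 4.34 ± 0.092 (SE), and lowered SM_b20902 (-7.28 ± 0.085) and SMa0203 (-8.11 ± 0.119). The rise of pckA was 1.02 ± 0.071 and that of fbaB 0.79 ± 0.067. The Entner-Doudoroff genes edd and zwf were higher on succinate than on glucose, by 1.20 ± 0.058 and 1.19 ± 0.052. cgmA rose by 2.98 ± 0.152, and SMc00777, a hypothetical protein, by 3.56. The phosphate transporter genes phoE, phoT, phoC and phoD fell by 2.44, 2.35, 2.34 and 2.23 on the log2 scale.

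Of the 18 TCA cycle genes 17 rose on succinate in pckR-, and 17 adjusted over the list alone (camera adjusted p = 5.62e-08, adjusted p = 0.165 with an estimated correlation), with aceA at 1.03, sdhB at 0.91 and lpdA1 at 0.91. All 26 respiratory chain genes rose, and 26 adjusted over the list alone (camera adjusted p = 1.37e-13, adjusted p = 0.204 with an estimated correlation), and all 10 ATP synthase genes rose, and 10 adjusted over the list alone (camera adjusted p = 3.19e-06, adjusted p = 0.0805 with an estimated correlation). Of the 15 genes of glycolysis and gluconeogenesis 12 rose and 1 fell, and 13 changed adjusted over the list alone (camera adjusted p = 4.31e-05, adjusted p = 0.181 with an estimated correlation), among them pgk (1.05), pykA (0.90) and pgi (0.79). Of 26 succinoglycan genes 21 rose and 2 fell, exsA and exoF3 (the latter chosen after its values were seen), and 23 changed adjusted over the list alone (camera adjusted p = 4.99e-11, adjusted p = 0.0805 with an estimated correlation). Of 51 flagellar and chemotaxis genes 46 fell, and 46 adjusted over the list alone (camera adjusted p = 1.85e-16, adjusted p = 0.142 with an estimated correlation).

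Other sugar and polyol, polyhydroxybutyrate and aromatic compound genes were lower in part on succinate in both strains. In pckR+ 11 of 31 genes for other sugars and polyols fell and 1 rose (camera adjusted p = 0.000822, adjusted p = 0.0913 with an estimated correlation). There 5 of 7 polyhydroxybutyrate genes (0.0369 and 0.257) and 2 of 9 aromatic compound genes (camera adjusted p = 0.237) fell. In pckR-, of the 31 genes for other sugars and polyols 20 fell and 3 rose (xylA, xylB and glpD, chosen after their values were seen), and 23 changed adjusted over the list alone (camera adjusted p = 0.000144, adjusted p = 0.181 with an estimated correlation). The sorbitol and mannitol transport genes smoF and smoG fell by 2.01 and 2.00, and the lactose transport genes lacE and lacF by 1.85 and 1.83 on the log2 scale. The 3 that rose were 1 without pckR- succinate replicate 2. Of the 7 genes for polyhydroxybutyrate, a carbon storage polymer, and acetoacetate 6 fell, and 6 adjusted over the list alone, with acsA1 at -0.70 and phbB at -0.62. camera passed this list (adjusted p = 0.0267, adjusted p = 0.257 with an estimated correlation), but not without pckR+ glucose replicate 1 (adjusted p = 0.0732) or replicate 2 (adjusted p = 0.0859). Of the 9 genes for protocatechuate and aromatic compounds 4 fell, and 4 adjusted over the list alone (camera adjusted p = 0.133). The 4 were 0 without pckR- glucose replicate 2 and 1 without pckR- succinate replicate 1.

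Of the 47 tested nodulation and nitrogen fixation genes 12 rose and 1 fell (nodD2, chosen after its values were seen) on succinate in pckR-, and 10 changed adjusted over the list alone. nodG rose by 0.74 and nifK by 0.64 on the log2 scale. camera passed the list (adjusted p = 0.0253, adjusted p = 0.235 with an estimated correlation), but not without pckR+ glucose replicate 1 (adjusted p = 0.215), pckR+ glucose replicate 2 (adjusted p = 0.251) or pckR- succinate replicate 1 (adjusted p = 0.0698). The 12 were 7 without pckR- glucose replicate 2 and 7 without pckR- succinate replicate 1, where 2 fell. In all, edgeR passed 2845 of 5815 genes in this comparison, 1343 higher and 1502 lower on succinate, 619 of them by more than 2-fold. The share of nodulation and nitrogen fixation genes that rose was near that of all tested genes. The larger side turned with DESeq2's size factors (1469 higher and 1390 lower) and with DESeq2's own test (1017 higher and 915 lower), and with library totals the split was 1130 higher and 1660 lower.

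**Figure D3:**
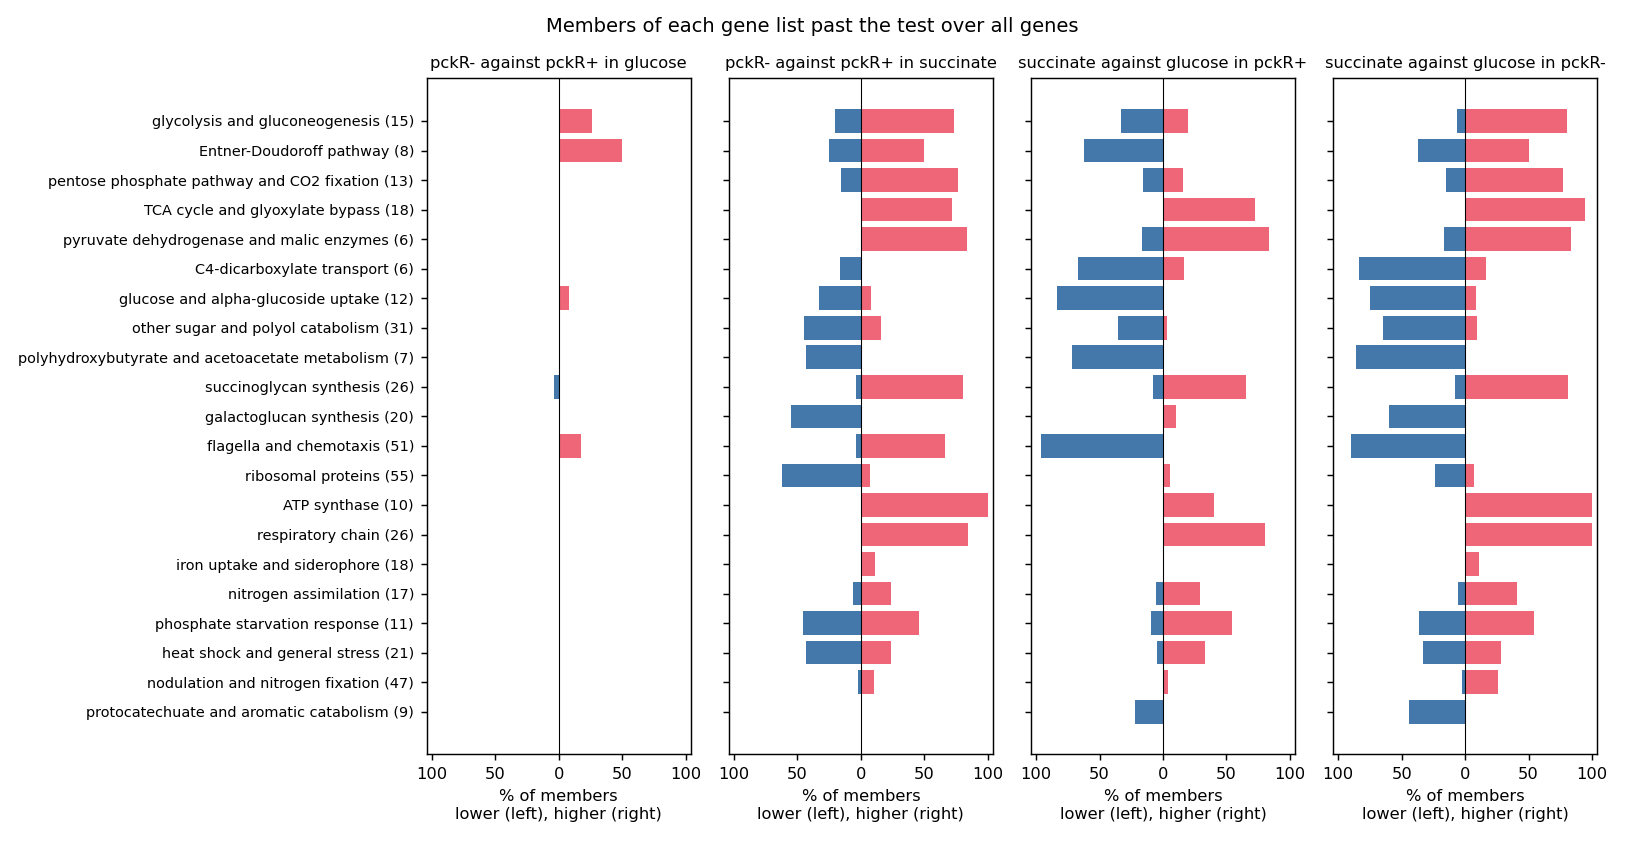
Percentage of the tested members of each of the 21 gene lists that were higher or lower past edgeR's test, in the 4 comparisons of 2 groups. All 10 ATP synthase genes rose in pckR- on succinate and on succinate in pckR-, and flagellar and chemotaxis genes fell on succinate in both strains, 49 of 51 in pckR+ and 46 of 51 in pckR-.

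The interaction, the strain effect on succinate minus that on glucose, asked for which genes the strain effect differed between the carbon sources. It was most negative for fbaB, with a log2 difference of -4.62 ± 0.103 (SE, adjusted p = 6.54e-17), and pckA, with -4.26 ± 0.108 (adjusted p = 4.32e-16), the genes that rose on glucose and fell on succinate in pckR-. It was positive for genes that rose in pckR- on both carbon sources and by more on succinate: edd with 3.95 ± 0.087, zwf with 3.90 ± 0.076 (adjusted p = 1.65e-17), pgl with 3.76, eda2 with 2.97 ± 0.106, mgsA with 2.43 and glk with 1.95. cgmA had the largest positive difference, 4.31 ± 0.256 (adjusted p = 7.39e-07). SMc03243 had -3.63 ± 0.274, phoE -3.13 ± 0.089, phoT -3.03, phoC -2.99 and phoD -2.92. The loss of the pckR transcript itself did not differ measurably between carbon sources, with a log2 difference of 0.05 (adjusted p = 0.921).

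Among the lists, 4 of the 8 Entner-Doudoroff genes had a positive and 1, eda1, a negative interaction (0 without pckR+ succinate replicate 1 or pckR- succinate replicate 2), and 5 passed adjusted over the list alone (camera adjusted p = 0.000138, adjusted p = 0.0910 with an estimated correlation). Of the 26 succinoglycan genes 21 had a positive and 1 a negative interaction, and 22 passed adjusted over the list alone (camera adjusted p = 1.90e-11, adjusted p = 0.0805 with an estimated correlation), with exoY at 1.39 ± 0.086 and exsA at -2.07. The interaction was negative for 10 of the 20 galactoglucan genes, and for 11 adjusted over the list alone (camera adjusted p = 1.15e-05, adjusted p = 0.0805 with an estimated correlation). It was positive for all 10 ATP synthase genes, and for 10 adjusted over the list alone (camera adjusted p = 7.13e-06, adjusted p = 0.0805 with an estimated correlation), and for 20 of the 26 respiratory chain genes, and 20 adjusted over the list alone (camera adjusted p = 3.74e-06, adjusted p = 0.264 with an estimated correlation). edgeR passed 1481 of 5815 genes, 758 with a positive and 723 with a negative difference, 318 of them by more than 2-fold. DESeq2 passed 845, and the split was 577 positive and 924 negative with library totals and 581 positive and 936 negative with the deposited scaling.

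The strain effects on glucose and on succinate share no libraries. Of the genes called in both, pckR, zwf, edd, pgl, eda2, glk, mgsA and SMc00404 went the same way and pckA and fbaB went opposite ways. In all 32 genes were called in both comparisons, 25 in the same direction and 7 in opposite directions. Higher in both were 19 genes, where independent lists of these sizes would share 4.69, and lower in both were 6, where they would share 2.54. The 6 include pckR itself, which carries the insertion in pckR-. Genes of a shared pathway, such as zwf, pgl and edd, do not vary independently, so the excess over these numbers was not tested. Across the 5815 genes, which are not independent replicates, the log2 fold changes on glucose and succinate had a Pearson correlation of 0.239 and a Spearman correlation of 0.112. The 25 were 61 without pckR+ glucose replicate 2, 12 without pckR- glucose replicate 1 and 8 without pckR- glucose replicate 2, and DESeq2 gave 13. The 7 were 2 without pckR+ glucose replicate 1, 26 without pckR+ glucose replicate 2 and 3 without pckR- glucose replicate 2, and DESeq2 gave 4 and an adjusted p under 0.01 gave 3.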

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

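The tests of scaling between libraries and of exchanged carbon source labels were chosen only after the result was seen. The strain effect was past the test in opposite directions on the carbon sources for pckA, with an interaction of -4.26 on the log2 scale, and for fbaB, with -4.62. Over 4 scalings between libraries the highest log2 fold change of either gene on succinate was -1.70. These scalings moved the median log2 fold change of all genes on succinate only between -0.10 and 0.00084. They could not have undone changes of this size, so this test could not have come out otherwise. Carbon source labels exchanged among the pckR- libraries are an unlikely cause. Each of these 4 libraries, whatever its label, lay above the pckR+ glucose libraries and below the pckR+ succinate libraries for both genes, by at least 3.14-fold. A candidate explanation that stays open is a regulator whose absence raises these genes on glucose and lowers them on succinate, but no binding or protein data were analysed here.

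The strain effect was also past the test in opposite directions for 5 further genes, each with an interaction past the test without each library in turn. The log2 difference was -1.12 for SMc00123, 1.68 for SMc02401, 1.77 for SMa1821, 1.02 for exoH and 1.35 for SM_b21440. Their calls on glucose depended on single libraries. Without pckR+ glucose replicate 1 the adjusted p on glucose was 0.0645 for SMc00123, 0.342 for SMc02401, 0.342 for SMa1821, 0.135 for exoH and 0.0746 for SM_b21440. Without pckR- glucose replicate 1 it was 0.0588 for SMc02401, 0.0689 for SMa1821 and 0.0676 for SM_b21440, and without pckR- glucose replicate 2 it was 0.552 for SMc02401, 0.552 for SMa1821, 0.455 for exoH and 0.366 for SM_b21440. On succinate the call of SMc02401 was lost without pckR- glucose replicate 1 (adjusted p = 0.0529), pckR- glucose replicate 2 (0.0508), pckR+ succinate replicate 2 (0.231), pckR- succinate replicate 1 (0.238) and pckR- succinate replicate 2 (0.0716).

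The predicted RNA rows of the deposited table, which were kept out of the comparisons of named genes, held 7.16% and 7.19% of all counts in the pckR- succinate libraries, against 5.34% to 5.89% in the other 6 libraries.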

How the results depend on the processing

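Predicted RNA rows kept in and the scaling of the deposited normalized counts were chosen after seeing the data; all other alternatives were fixed before. The number of genes called on glucose was 37 and moved to 17 with DESeq2 and 14 at an adjusted p under 0.01, and ranged from 11 to 111 when single libraries were left out. On succinate 2243 genes became 1468 with DESeq2 and ranged from 1684 to 2365 without single libraries. The carbon source effect in pckR+ went from 1644 to 1006 with DESeq2 and 1095 at an adjusted p under 0.01, with a range of 1143 to 1596, that in pckR- from 2845 to a range of 2230 to 2974, and the interaction from 1481 to 845 with DESeq2, with a range of 1182 to 1455. The 25 genes with the same direction of strain effect on both carbon sources were 13 with DESeq2 and 10 at an adjusted p under 0.01, with a range of 8 to 61. Of 105 list tests 55 passed, 0 with an estimated correlation (28 at an unadjusted p under 0.05; 5 without pckR+ glucose replicate 1 and 4 without pckR+ glucose replicate 2), and 49 to 57 without single libraries. The cause of these shifts was not tested, except that a stricter threshold passes fewer genes and a left-out library leaves its group with 1 library, assumed to vary like the other groups. Apart from the replicate block, all other settings kept these counts within 1.5 times. Of 566 values of single genes 441 kept their call under every setting, 100 lost it under at least 1, and 0 changed direction while called.

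Replicate numbers were not taken to pair the libraries, since deviations of same-numbered libraries correlated above 0.1 in 3 of 6 pairs of groups only, with a range of -0.00244 to 0.162. The correlation was positive in 5 of the 6, a hint from the data, not from the design. With the replicate block edgeR called 80 genes for the strain effect on glucose, 2407 for that on succinate, 1821 and 2978 for the carbon source effect in pckR+ and in pckR-, and 1685 for the interaction. The agreement in direction rose to 52 genes, with 18 in opposite directions, and 56 list tests passed. Depth limits the genes of lowest count, and the simulated 1.5-fold changes were recovered less often than larger ones in each comparison. Not run were the fits with rRNA and tRNA rows kept in, of which the table has 0, and the pseudocount and low-value filter, which were meant for normalized values.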

Other observations

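Of the tests below, that of scaling of the phosphate genes and that of the pst genes were chosen only after the result was seen. Genes of the chromosome and of the plasmids pSymA and pSymB changed in different proportions in pckR- on succinate. On the chromosome 986 genes were higher and 488 lower, on pSymA 87 higher and 175 lower, and on pSymB 114 higher and 393 lower, with median log2 fold changes of 0.085, -0.098 and -0.17 over all tested genes of each. The split on the chromosome depended on the scaling: it was 735 higher and 703 lower with library totals, and 719 higher and 756 lower, with a median of -0.014, with the deposited scaling, while lower genes outnumbered higher ones on pSymA and pSymB under these scalings too, 233 to 58 and 490 to 86 with library totals. The share of counts on pSymB was 11.4 and 11.3% in pckR+ on glucose, 10.7 and 11.0% in pckR- on glucose, 8.62 and 8.78% in pckR+ on succinate, and 7.02 and 6.96% in pckR- on succinate. Among the predicted RNAs, predictedRNA248 (2357128 to 2356782, minus strand in the deposited coordinates) held 2.98 and 2.93% of all counts in the pckR- succinate libraries and 1.75 to 1.93% in the other 6. In the fit with predicted RNA rows kept in, its log2 fold change in pckR- on succinate was 0.74 ± 0.049 (SE, n = 2 libraries per group, edgeR adjusted p = 2.89e-09). There 165 of 461 tested predicted RNAs were called in that comparison, near the share of 38.6% of named genes called without these rows.

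A set of 9 genes, chosen after their values were seen, differed between replicates of pckR+, and its copper genes also between those of pckR- on succinate. By annotation 3 belong to zinc uptake, 4 are copper proteins and 2 are hypothetical. In the order pckR+ glucose, pckR- glucose, pckR+ succinate and pckR- succinate, replicate 1 before replicate 2, znuA had 93.5, 3328, 4071, 4123, 40.8, 171, 4782 and 4553 CPM, and the hypothetical gene SMc03799 had 11.0, 1026, 1343, 1351, 5.85, 17.9, 1211 and 1128 CPM. SMc02283, annotated as a copper-containing oxidoreductase, had 1235, 125, 87.7, 72.5, 612, 232, 109 and 45.3 CPM. Each copper gene was higher in replicate 1 than in replicate 2 in every group. The copper oxidase gene SMa1041 had 132 and 48.2 CPM in pckR- on succinate. With edgeR 0 of the 9 passed in any comparison, although 5 had an unadjusted p under 0.05 for the strain effect on succinate and 0 in the other 4 comparisons. DESeq2 passed 5 for the strain effect on succinate and 3 for the carbon source effect in pckR+, and the groups compared alone passed 5 for the former and 3 for the carbon source effect in pckR-. Without pckR+ glucose replicate 1 edgeR passed 5 for the strain effect on succinate, 5 for the carbon source effect in pckR+ and 4 for the interaction, and without pckR+ glucose replicate 2 it passed 2 for the strain effect on glucose and 5 for that on succinate.

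The strain effect passed the test for 37 genes on glucose and 2243 on succinate. The spread between the pckR+ glucose libraries is unlikely as the whole cause, since without pckR+ glucose replicate 1, which had the lowest mean correlation with the other glucose libraries, the glucose count was 31, and without replicate 2 it was 111. It was 19 without pckR- glucose replicate 1 and 11 without pckR- glucose replicate 2. A difference in depth is unlikely too: with all libraries thinned to 3278966 counts, the total of the smallest, 2009 genes passed on succinate and 29 on glucose, a ratio of 69.3. The authors' deposited table has the opposite order, with a q-value under 0.05 for 3243 named genes on glucose and 1376 on succinate, by a test not given in the sources used here. A larger dependence on pckR during growth on succinate may account for the difference in edgeR's counts, as a hypothesis found and tested on the same libraries. Other differences between the succinate cultures of the strains, such as growth rate, stay open and were not tested.

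In pckR- on succinate phoC, phoD, phoE and phoT fell and pit rose. The smallest absolute log2 fold change of the 5 genes over 4 scalings between libraries was 2.00. These scalings moved the median log2 fold change of all genes on succinate only between -0.10 and 0.00084, so this test could not have come out otherwise. The 5 genes are known targets of the phosphate regulator PhoB, which raises phoCDET and lowers pit when phosphate is scarce. A hypothesis is therefore lower PhoB activity in pckR- on succinate. It predicts lower phn genes for phosphonate use, and all 7 tested, phnG, phnH, phnI, phnJ, phnK, phnL and phnM, fell, with a median log2 fold change of -1.97 and a range of -2.16 to -1.67. A fall of the pst phosphate transporter genes and phoU would also be predicted, but pstC, pstA, pstB and phoU rose, with a median of 0.32. Their edgeR adjusted p ran from 4.03e-06 to 0.00314, and pstS had no tested row. The rises of the pst genes and phoU, from 0.28 to 0.46 on the log2 scale, argue against an extension of the hypothesis to these genes. The phn genes go with the hypothesis, which stays open.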
